A study of Mus musculus with 6 samples.

How the data were processed

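Bone marrow neutrophils of C57BL/6 mice were loaded with 250 nM of the membrane potential dye DiBAC4(3), an anionic dye that enters depolarized cells and fluoresces there, and were stimulated with 100 nM ionomycin, a calcium ionophore. Per the labels' protocols, 20000 cells of the depolarized and of the polarized population were sorted into lysis buffer between 2 and 4 minutes after stimulation, and cDNA was made with a low-input SMARTer kit from the RNA. The series has 6 libraries, 3 of depolarized and 3 of polarized cells. The design text of the series describes them as 3 biological replicate pairs, and the code that ends each title (180206, 180214 or 180220) is shared by a depolarized and a polarized library. The pairs are called A (180206), B (180214) and C (180220) in the text. Groups were taken from the response label of each sample. The titles also hold a run label, which reads run 2 in 5 libraries and run 1 in the depolarized library of pair 180214. Its meaning is not given in the sources used here, and with 1 library under a label of its own it could not be entered as a batch.

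Each library has a table with a raw count, a CPM and an RPKM per gene, for 41388 genes. Per the submitters' processing notes, the tools used were bcl2fastq, STAR (version 2.0.4b), Subread and featureCounts (version 1.45), with genome build GRCm38. The deposited counts are whole numbers per gene and are not normalized. The deposited CPM values equal those recomputed from the counts and the library totals (largest difference 4.8e-10), and the deposited RPKM values equal those CPM values per kilobase of the listed gene length. Strand setting, treatment of reads that match several places and annotation release are not given in the sources used here. Reads that fall on overlapping exons or on near-identical copies can therefore have been dropped, shared or assigned to either gene. Exons of the genes named below were compared with those of all other genes in GENCODE M21, which holds 40340 of the gene identifiers, of which 40244 overlap the position given in the files. Symbols were taken from the reference table for 40254 genes. The other 1134 genes held 0.131% of all counts. No row without a gene was present.

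Total counts ran from 16904969 to 20381489 per library. At this depth 3 counts, the number used as the detection floor, correspond to 0.0536 CPM over the 3 polarized libraries and 0.0531 CPM over the 3 depolarized libraries. Intervals and floors cover counting error only, since PCR copies were not told apart by molecular identifiers.

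Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 9971 genes holding 99.9% of the counts. Libraries were scaled with TMM factors, and the quasi-likelihood F test was run with default settings on a design with the replicate code as a block and the group, which leaves 2 residual degrees of freedom. Fold changes are depolarized minus polarized on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are approximate, the fold change divided by the square root of its F statistic. Pairing rests on the design text. As a check, deviations from the group means were correlated between the libraries that share a code: r across genes was 0.08 for code 180206, 0.27 for 180214 and 0.03 for 180220, so the values alone show little of the pairing. For 180220 the highest correlation of the polarized library with a depolarized library of another code, 0.135, was above that within the code. The values therefore give the pairing for this code no support. They cannot decide it, since deviations from a group mean depend on each other and only the polarized library was compared across codes. All pairs of libraries within a group differed by more than sampling noise, with chi-square divided by its degrees of freedom between 32.9 and 114, so no library was treated as a copy of another.

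Gene lists were tested with limma 3.58.1 (camera, preset inter-gene correlation of 0.01) on log2 CPM with a prior count of 2, with the replicate block and with adjustment over the 30 lists that had 3 or more tested members. Of 32 lists written, basophils and mast cells and megakaryocytes and platelets had 2 tested members each and were not tested. Beside it, camera with an estimated correlation and fry were run. The list members Vamp7, Munc13, Ighd, Iglc1 and Ahsp were not analysed here. Lists, design, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 12 called genes per direction with the largest fold change, a mean log2 CPM of at least 3, a symbol and the same sign in all 3 pairs, up to 4 called members with the lowest p from each list that differed or held a called gene, and Stim1, Stim2, Orai1, Orai2, Orai3, Trpm4, Kcnn4, Kcnj2, Hvcn1, Cybb, Ly6g and Cxcr2 whatever their values. By the first part of the rule, 7 genes qualified in each direction. All other genes named in the text, those counted over a list alone among them, were chosen after their values were seen.

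The fit was tested on simulated data drawn from the means and library sizes of these libraries, over 5 draws of the depolarized and polarized comparison. The means came from a fit on the replicate code and the dispersions from the blocked fit, so differences between pairs were built in. Each draw had 200 changed genes with a mean log2 CPM of at least 3, and 9675 genes were tested on average. With the block, 80.2% of genes changed 2-fold and 100% of those changed 4-fold were called, and 3.82% of calls were false. Without the block the shares were 36.0% and 99.2%, and 0.146% of calls were false. The draws therefore cannot decide whether the block is right for the real libraries. A list shifted by -1 on the log2 scale was found in 5 of 5 draws by camera with the preset correlation and in 3 by fry. Camera with an estimated correlation found it in 0, so it had little power in these draws. Genes were drawn independently of each other, so the draws cannot tell whether the preset of 0.01 holds for the real lists. In the real data the estimated correlation was 0.04 for the primary granule, 0.14 for the early-stage, 0.35 for the cell cycle and 0.70 for the secondary granule list.

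Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a stricter filter (at least 5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, robust dispersion estimates, no replicate block, leaving out each pair, leaving out each library without the block, a threshold of 0.10 and a minimum log2 fold change of 1. For lists, a prior count of 0.5 was also tried. The older edgeR quasi-likelihood method, meant as an alternative, is the default of this version, so the newer method was added after seeing the data. Also added then were the unblocked fits with DESeq2 and with the newer edgeR method, and a fit in which the trend of each library's deviation on gene length (loess, span 0.3) was removed through the offsets. Figures were drawn with matplotlib 3.10.9.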

Results

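RNA was sequenced from bone marrow neutrophils of C57BL/6 mice that had been loaded with a membrane potential dye, stimulated with ionomycin and sorted by their response into a depolarized and a polarized population. Ionomycin raises cytosolic calcium, empties intracellular stores and so opens store-operated calcium entry. Each population was represented by 3 libraries that form 3 biological replicate pairs, called A, B and C. Depth was similar in all libraries, with 19323965, 17031149 and 19613539 counts in the polarized libraries of pairs A, B and C and 20381489, 19186785 and 16904969 in the depolarized ones. Between 15527 and 16005 genes had at least 1 count. Neutrophil transcripts were abundant in every library: S100a8, S100a9 and Retnlg were, with the actin gene Actb, among the 5 most abundant genes in all 6. The 10 most abundant genes took 31.3% to 35.3% of the counts. Mitochondrial transcripts made up 0.547% to 0.743% of counts.

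The comparison asks which transcripts differ between neutrophils that depolarized and those that were polarized during store-operated calcium entry. Genes said to rise or fall differ between these sorted populations, all from stimulated cells, and no change over time was measured. Depolarized cells held less mRNA for 5 of 13 tested genes of primary granules, 12 of 28 of the early neutrophil stage and 5 of 31 of the cell cycle. These lists were lower by camera with a preset correlation, though not with an estimated one (adjusted p = 0.451 for each), and the cell cycle list was lost under a stricter filter (adjusted p 0.970). Myeloperoxidase (Mpo), which makes hypochlorous acid, was 39.3-fold lower and neutrophil elastase (Elane) was 50.5-fold lower in depolarized than in polarized cells. Among secondary granule genes, lactotransferrin (Ltf) was 2.60-fold, the cathelicidin gene Camp 2.74-fold and ficolin B (Fcnb) 35.9-fold lower, and 16 of 20 were not called. A smaller set of genes rose by about 2-fold, among them the receptor genes Gpr35 and Clec4n and the metalloreductase gene Steap4. Of 9971 genes tested, 8 were higher and 24 lower in depolarized cells by the edgeR quasi-likelihood test with the pairs as a block, and all 32 had the same sign in all 3 pairs. These counts depend on the block: without it edgeR called 0 genes in either direction, with 511 genes at an unadjusted p under 0.05 against 656 with it, while DESeq2 without the block called 5 higher and 18 lower. Of those, 1 higher and 15 lower were among the 8 and 24. With the pairs kept and the trend of each library on gene length removed, 0 genes were called higher and 8 lower. Leaving out pair A, B or C gave 25, 9 and 500 genes higher and 74, 36 and 518 lower.

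Primary granule enzymes gave the largest differences among abundant genes. Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413 in GRCm38) was at 59.6 ± 74.5 CPM (SD, n = 3) in polarized and 2.12 ± 3.24 CPM in depolarized cells, a log2 fold change of -5.30 with a standard error of 0.29 and an edgeR adjusted p of 1.96e-08. The polarized level was 13.4 CPM in pair A, 19.8 CPM in pair B and 146 CPM in pair C. The difference within each pair was -5.02, -5.98 and -4.84 on the log2 scale, and the fitted value was -5.97 without pair C. Elane (chromosome 10, 79886312 to 79888216) went from 53.7 ± 49.4 to 1.78 ± 2.86 CPM, with a log2 fold change of -5.66 ± 0.41 (SE) and an edgeR adjusted p of 8.32e-07. The difference of Elane was -5.66, -7.52 and -4.62 on the log2 scale in pairs A, B and C, and the fitted value was -7.57 without pair C and -5.08 without pair B. Robust edgeR did not call Elane (adjusted p 0.0523). The neighbouring serine protease gene Prtn3 was lower by 3.55 on the log2 scale as fitted, from 8.92 ± 6.47 to 0.842 ± 0.757 CPM. Ms4a3, a membrane protein gene of granulocyte and monocyte precursors, went from 9.21 ± 5.54 to 0.352 ± 0.333 CPM, a log2 fold change of -4.77, or -4.07 without pair B. Cathepsin G (Ctsg), named after its values were seen, held 294 counts over the polarized and 5 over the depolarized libraries. In the list of primary granule genes, 5 of 13 tested members fell, 0 rose and 8 were not called, and 6 fell when adjusted over the list alone. The median log2 fold change of that list was -0.88, and the list was lower by camera with an adjusted p of 3.10e-11 (adjusted p = 0.451 with an estimated correlation). The median difference of its members was -0.83, -0.71 and -1.67 in pairs A, B and C, and the polarized library of pair C stood apart from the rest.

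**Figure D1:**
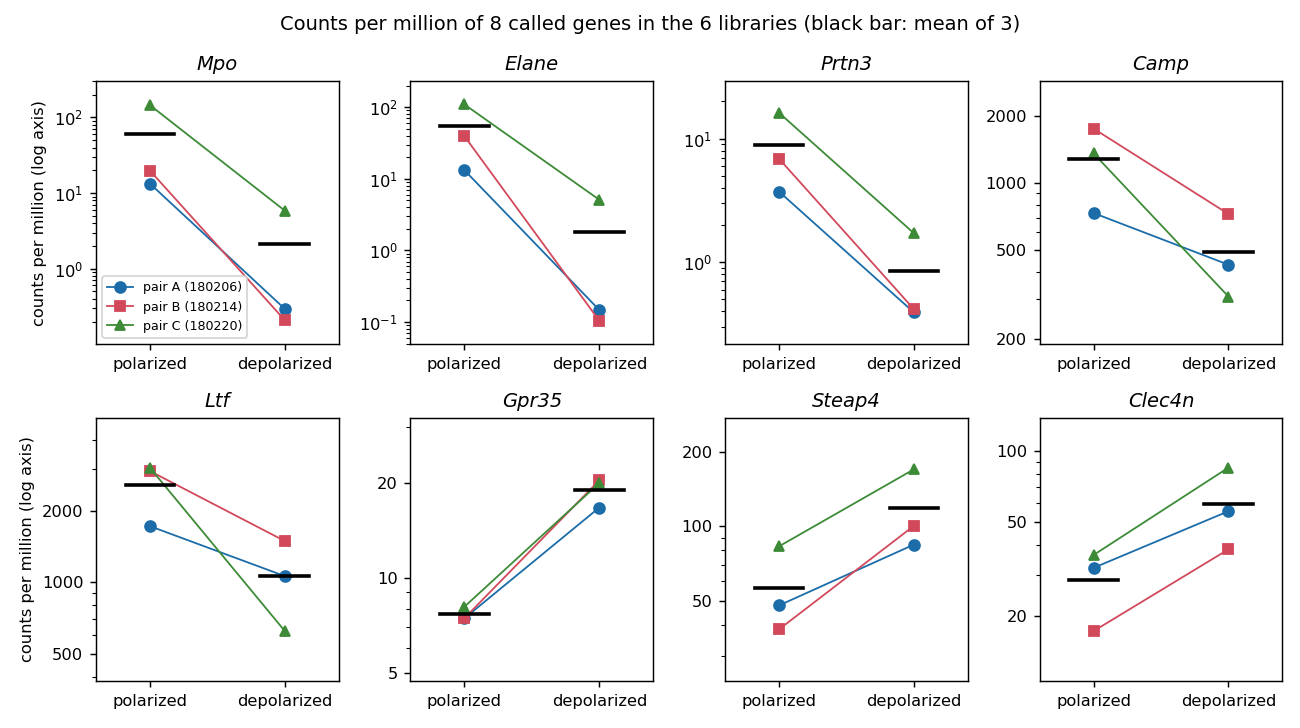
CPM of 8 called genes on log axes, with a line for each replicate pair from its polarized to its depolarized library and a black bar at each group's mean of 3 libraries. Mpo, Elane, Prtn3, Camp and Ltf go down and Gpr35, Steap4 and Clec4n go up in all 3 pairs, and the polarized library of pair C holds the highest Mpo level, 146 CPM.

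Genes of the early neutrophil stage were lower as a list. Of 28 tested members, 12 fell, 0 rose and 16 were not called, and 15 fell when adjusted over the list alone, but 19 of the 28 also stand in another list, among them the granule enzymes. The median was -0.95 and camera gave an adjusted p of 9.12e-20 (adjusted p = 0.451 with an estimated correlation). The median difference of the early-stage members was -0.62, -0.71 and -1.86 in pairs A, B and C, and the polarized library of pair C stood apart from the rest. Macrophage (median -0.87) and plasma cell markers (median -1.66) also lay lower in depolarized cells, though the macrophage list changed direction under the stricter filter. Ficolin B (Fcnb), a pattern recognition lectin, went from 15.8 ± 16.1 to 0.469 ± 0.543 CPM, a log2 fold change of -5.17 ± 0.46 (SE) with an edgeR adjusted p of 1.17e-05. In the secondary granule list 4 of 20 members (Fcnb, Chil3, Camp and Ltf) fell and 16 were not called, 8 fell when adjusted over the list alone, and 19 of 20 were fitted below 0. Camp went from 1282 ± 515 to 488.1 ± 214 CPM (log2 fold change -1.46 ± 0.25, SE, edgeR adjusted p 0.0144) and Ltf from 2573 ± 734 to 1061 ± 435 CPM (log2 fold change -1.38 ± 0.28, SE, edgeR adjusted p 0.0427). With DESeq2 and the same block, Camp (adjusted p 0.204), Ltf (0.947) and Chil3 (0.149) were no longer called, and Ltf was also lost with robust edgeR (adjusted p 0.248) and the stricter filter (0.0533). The chitinase-like gene Chil3 went from 457.2 ± 250 to 145.7 ± 5.91 CPM, and its value is uncertain because it has close paralogs whose reads may have been counted with it. The median of the secondary granule list was -0.46, with a camera adjusted p of 9.05e-10 (adjusted p = 0.558 with an estimated correlation). The median difference of its members was -0.11, -0.44 and -0.90 in pairs A, B and C, and without pair C Camp was fitted at -1.01, Ltf at -0.83 and Chil3 at -1.11. The gelatinase granule and secretory vesicle list was not called by camera (adjusted p 0.875), with a median of 0.05. Of its 16 members 0 were called (1, Itga4, when adjusted over the list alone). The median difference of its members was 0.18, 0.16 and -0.41 in pairs A, B and C, so the pairs differed in direction.

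Cell cycle genes that fell did so from low absolute levels. Of 31 tested members, 5 fell (Cdk1, Birc5, Top2a, Ube2c and, named after its values were seen, Rrm2), 0 rose and 26 were not called, and 14 fell when adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, went from 2.35 ± 1.72 to 0.202 ± 0.134 CPM, which rests on 134 and 11 counts over 3 libraries each. Birc5 was 12.5-fold lower, the topoisomerase gene Top2a 5.95-fold lower and the ubiquitin-conjugating enzyme gene Ube2c 11.0-fold lower, with edgeR adjusted p of 0.0109, 0.0121 and 0.0393. Without pair C, Birc5 was fitted at -4.50, and Ube2c was fitted at -2.73 and no longer called (edgeR adjusted p 0.0522), against log2 fold changes of -3.65 and -3.45 with all pairs. Mki67, the gene of the proliferation antigen Ki-67 and also named afterwards, was at 9.64 ± 2.53 and 8.44 ± 1.10 CPM and was not called (edgeR adjusted p 1). Other members with higher levels, also named afterwards, were not called either: Kif23 was at 43.9 ± 1.51 and 58.6 ± 8.48 CPM, Cenpa at 18.4 ± 1.79 and 17.6 ± 2.53 CPM and Cdc45 at 14.6 ± 1.55 and 13.9 ± 4.08 CPM, and Mcm4 had a log2 fold change of 0.17. The list's median was -1.60 and its camera adjusted p was 2.56e-16 (adjusted p = 0.451 with an estimated correlation, and 0.970 under the stricter filter). The median difference of its members was -0.84, -0.34 and -1.87 in pairs A, B and C, and the polarized library of pair C stood apart from the rest. Pbk, Asf1b, Kif22, Tipin and Prim1, which act in mitosis or DNA replication and were named after their values were seen, were also called lower. Prim1, a DNA primase subunit gene, had 63 counts over the polarized libraries and 0 over the depolarized ones, at least 21.2-fold lower against 3 counts over the group. Alg8, an endoplasmic reticulum glycosyltransferase gene also named afterwards, had 62 and 2 counts, a ratio of 31.3 with a 95% counting interval (exact binomial) of 8.30 to 264.

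Of the 8 genes that rose, 7 were named by the rule. Gpr35, a G protein-coupled receptor gene (chromosome 1, 92950865 to 92986391), rose from 7.67 ± 0.377 to 19.0 ± 2.00 CPM, a log2 fold change of 1.23 ± 0.22 (SE) with an edgeR adjusted p of 0.0172, and its libraries did not overlap between groups. Clec4n, which encodes the fungal receptor dectin-2, rose from 28.6 ± 9.96 to 59.6 ± 23.6 CPM (log2 fold change 0.99 ± 0.18, SE, edgeR adjusted p 0.0218). Steap4 rose from 56.5 ± 23.5 to 118 ± 45.5 CPM, and Pmaip1, which encodes the pro-apoptotic protein Noxa, from 24.5 ± 9.80 to 49.5 ± 8.48 CPM. The immune receptor gene Cd244a rose from 23.3 ± 7.58 to 46.3 ± 7.20 CPM and the transporter gene Abcg3 from 8.16 ± 2.00 to 17.7 ± 3.92 CPM. The lipoxygenase gene Alox15 rose 5.17-fold, from 3.60 ± 2.76 to 16.6 ± 7.65 CPM, with pair differences of 4.77, 2.18 and 0.88 on the log2 scale in pairs A, B and C. Its log2 fold change of 2.37 became 1.56 without pair A and 3.07 without pair C. Alox15 was not called with DESeq2 (adjusted p 0.504), robust edgeR (0.866) or the stricter filter (0.0529), and Abcg3, Pmaip1 and Cd244a were also lost under that filter (edgeR adjusted p 0.0884, 0.0588 and 0.0592). Abcg3 lost its call without pair A as well (log2 fold change 1.01, edgeR adjusted p 0.174). Serpinb2, named after its values were seen, had 2 counts over the polarized and 57 over the depolarized libraries, a ratio of 28.2 with a 95% counting interval (exact binomial) of 7.47 to 239. Its value is uncertain because 12.4% of its exon length is shared on the same strand with Serpinb10, which held 1939 counts. Without pair B 6 of the 7 rising genes named by the rule (Gpr35, Abcg3, Steap4, Pmaip1, Clec4n and Cd244a) were no longer called, with edgeR adjusted p between 0.336 and 1, though all stayed above 0.

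Several lists of mature neutrophil and response genes were higher by camera, with small shifts and almost no member called alone. Interferon-stimulated genes had a median log2 fold change of 0.22 with 32 of 36 members fitted above 0 and 0 called in either analysis (camera adjusted p 4.96e-06, adjusted p = 0.451 with an estimated correlation). Late-stage neutrophil genes had a median of 0.16, 0 of 35 called, and 5 higher when adjusted over the list alone (Ccrl2, Wfdc17, Csf1, Cd101 and Il1b), with a camera adjusted p of 0.00523 (adjusted p = 0.558 with an estimated correlation, 0.0972 without pair A and 0.134 without pair B). Among those genes, named after their values were seen, Cd101, a surface marker of mature neutrophils, was at 221 ± 29.2 and 359 ± 46.1 CPM, and the interleukin gene Il1b at 650.3 ± 97.3 and 1014 ± 67.0 CPM. Chemoattractant and phagocytic receptor genes had a median of 0.16, 1 of 30 called (Clec4n) and 2 when adjusted over the list alone, with a camera adjusted p of 0.00255 (adjusted p = 0.623 with an estimated correlation, 0.181 without pair A and 0.0905 without pair B). Inflammatory cytokine genes had a median of 0.09 and 0 of 29 called in either analysis (camera adjusted p 0.00539, adjusted p = 0.451 with an estimated correlation and 0.202 without pair C). Immediate early genes had a median of 0.13, 0 of 23 called and 1 (Atf3) over the list alone (camera adjusted p 0.0131, adjusted p = 0.718 with an estimated correlation, 0.0924 without pair A and 0.813 without pair C), and apoptosis and stress genes a median of 0.16 and 0 of 25 called in either analysis (camera adjusted p 0.0229, adjusted p = 0.451 with an estimated correlation, 0.289, 0.0936 and 0.0633 without pairs A, B and C, and 0.271 under the stricter filter). In all, 15 of 30 lists were called, 6 higher and 9 lower. With an estimated correlation 0 were called, and fry called 1 (stroma and endothelium), while its test of changes in either direction called 8. Of the other splits of the 6 libraries into 3 against 3, the 3 that part all pairs gave 6 to 13 called lists with the preset correlation, and the 6 that part 1 pair gave 9 to 15.

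**Figure D2:**
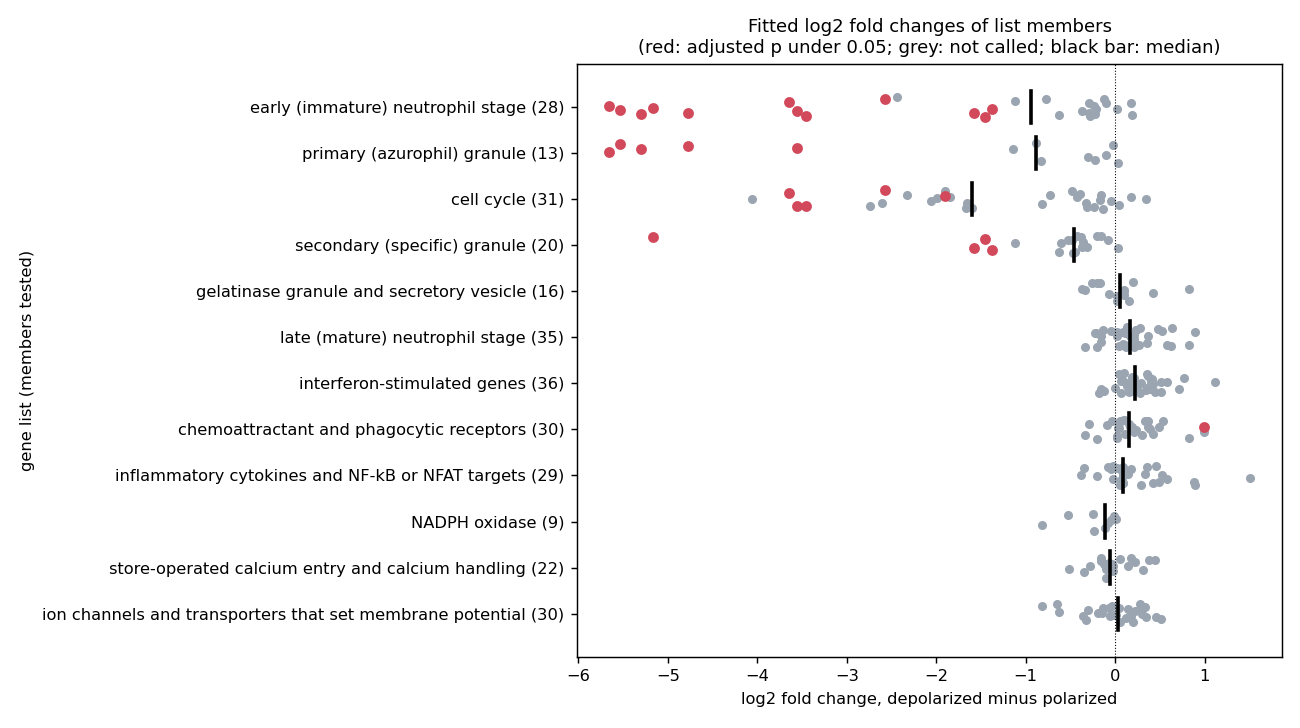
Fitted log2 fold changes, depolarized minus polarized, of the tested members of 12 lists, with called members in red, uncalled members in grey and each list's median as a black bar. Early-stage, primary granule and cell cycle members reach far below 0, while the calcium entry and ion channel lists centre near 0 with no called member.

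Genes of store-operated calcium entry itself did not pass the test. The endoplasmic reticulum calcium sensor gene Stim1 was at 47.6 ± 8.51 CPM in polarized and 47.0 ± 8.41 CPM in depolarized cells (log2 fold change -0.09 ± 0.18, SE), and Stim2 at 32.8 ± 4.05 and 23.9 ± 2.47 CPM (log2 fold change -0.52 ± 0.19, SE). Stim2 was below 0 in 3 of 3 pairs with an edgeR adjusted p of 0.506. The channel subunit genes Orai1 and Orai2 had log2 fold changes of -0.02 ± 0.18 and -0.07 ± 0.18 (SE), and Orai3 had 0.38 ± 0.18, above 0 in 3 of 3 pairs with an edgeR adjusted p of 0.751. Without pair C, Stim2 (-0.62, edgeR adjusted p 0.00156) and Orai3 (0.40, edgeR adjusted p 0.0280) were called, and without pair B Orai1 was fitted at 0.06. Calls without a pair, here and below, rest on fewer residual degrees of freedom. Of 1010 genes called without pair C and also tested with all pairs, 411 (40.7%) had the same sign in pair C. In the calcium entry and handling list, 0 of 22 members were called in either analysis, the median was -0.05 and the camera adjusted p was 0.875.

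Genes that can set the membrane potential gave a similar result. The channel gene Trpm4 had 0 counts over the polarized and 2 over the depolarized libraries, and the calcium-activated potassium channel gene Kcnn4 had 1 and 7, so both stayed below the filter and a difference was not detectable at this depth. The inward rectifier gene Kcnj2 was at 24.5 ± 7.68 and 27.3 ± 2.86 CPM, and its log2 fold change of 0.12 became -0.10 without pair C. The voltage-gated proton channel gene Hvcn1 had a log2 fold change of -0.82 ± 0.27 (SE) and an edgeR adjusted p of 0.406, with pair differences of -0.01, -0.84 and -1.64 in pairs A, B and C. It was called without pair A (-1.24, edgeR adjusted p 0.0346), and 44.2% of its exon length is overlapped on the opposite strand by Tctn1, which held 143 counts against 1431. In the ion channel and transporter list 0 of 30 members were called in either analysis, with a camera adjusted p of 0.989. Its median was 0.03 and its mean -0.01, which differ in sign.

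**Figure D3:**
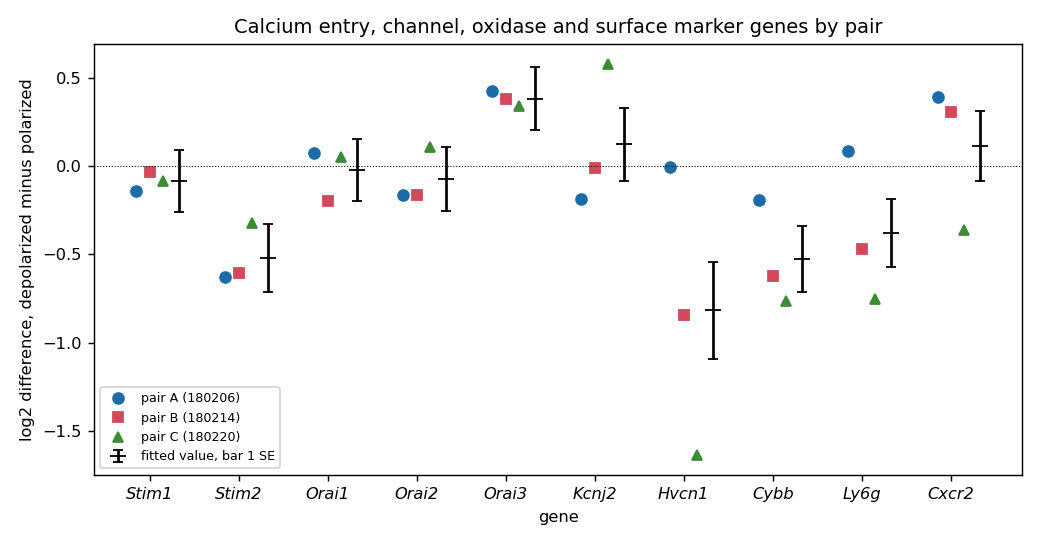
Log2 difference, depolarized minus polarized, within each of the 3 pairs for 10 genes reported whatever their values, with the fitted value and a bar of 1 standard error in black. Stim2 lies below 0 and Orai3 above 0 in all 3 pairs, Stim1, Orai1 and Orai2 lie within 0.2 of 0, and Hvcn1 and Kcnj2 differ between pairs.

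The oxidase subunit gene Cybb was at 1181 ± 233 and 870.4 ± 246 CPM (log2 fold change -0.53 ± 0.19, SE, edgeR adjusted p 0.456), and without pair C it was called (-0.41, edgeR adjusted p 0.00210). The NADPH oxidase list, with 0 of 9 members called in either analysis and a median of -0.12, had a camera adjusted p of 0.0558. It was called by camera without the replicate block and under the stricter filter. Surface marker genes of neutrophils did not pass the test: Ly6g was at 460.5 ± 89.6 and 367.0 ± 31.0 CPM (log2 fold change -0.38 ± 0.19, SE, edgeR adjusted p 0.816), and the chemokine receptor gene Cxcr2 at 2620 ± 415 and 2945 ± 159 CPM (0.11 ± 0.20, SE, edgeR adjusted p 1). Without pair C Cxcr2 was called at 0.35 (edgeR adjusted p 0.00872), and without pair A it was fitted at -0.03. The lists of glycolysis (median -0.02, 24 members), degranulation machinery (0.00, 21 members), cytosolic ribosomal proteins (0.00, 74 members) and the nuclear-encoded respiratory chain (-0.06, 75 members) had 0 called members in either analysis and camera adjusted p of 0.910, 0.898, 0.898 and 0.0790. The medians of the degranulation and ribosomal lists lie close to 0, and their means (-0.05 and -0.03) differ from them in sign. Camera called the respiratory chain list without the replicate block, under the stricter filter and without pair A, and the ribosomal list without pair C.

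Markers of other cell types moved with the groups in part. The immunoglobulin gene Igha was lower in depolarized cells (27.0 ± 16.9 against 1.52 ± 1.79 CPM, log2 fold change -4.31 ± 0.61, SE, edgeR adjusted p 0.00248), the called member of 4 plasma cell genes (2 when adjusted over the list alone, median -1.66, camera adjusted p 0.0229, adjusted p = 0.580 with an estimated correlation). The fitted value of Igha ran from -3.19 without pair A, whose depolarized library held 0 counts of it, to -5.38 without pair B, and Igha was not called with DESeq2 (adjusted p 0.592) or robust edgeR (0.861). Nkg7, a cytotoxic granule gene on the T and NK cell list, was lower (5.51 ± 5.39 against 0.270 ± 0.381 CPM, log2 fold change -4.65 ± 0.47, SE, edgeR adjusted p 3.21e-05), while 3 of the 4 tested members were not called (median -0.44, camera adjusted p 0.0131, adjusted p = 0.451 with an estimated correlation, 0.172 without pair C and 0.107 without the block). Nkg7 was fitted at -5.39 without pair C. Macrophage markers had a median of -0.87 with 0 of 13 called (camera adjusted p 0.000378, adjusted p = 0.502 with an estimated correlation and 0.127 without pair C), and over the list alone Axl, Vcam1 and C1qb were lower and Adgre1 higher. Under the stricter filter the macrophage list changed direction (camera adjusted p 0.605). The stroma and endothelium list (3 members, median -0.58, camera adjusted p 0.0484, adjusted p = 0.502 with an estimated correlation and 0.0580 to 0.202 without a pair) and the mitochondrially encoded genes (7 members, median -0.27, camera adjusted p 0.0131, adjusted p = 0.718 with an estimated correlation, 0.218 without pair B and 0.364 without pair C) were lower with 0 called in either analysis. The stroma call was also lost without the block (camera adjusted p 0.0900), with a prior count of 0.5 (0.0502) and with the gene length trend removed (0.0545). B cell (12 members, median -0.41, camera adjusted p 0.0520) and erythroid genes (7 members, median 0.04, camera adjusted p 0.875) had 0 called in either analysis. The B cell list was called by camera with DESeq2 size factors, with upper-quartile scaling, without the replicate block and without pair C. Monocyte genes (11 members, median 0.14, mean -0.57, camera adjusted p 0.697) had 0 called and, over the list alone, 2 higher and 2 lower, so the median and the mean differ in sign, as they do for stem and progenitor genes. Stem and progenitor genes (5 members, median 0.39, mean -0.02, camera adjusted p 0.676) had 0 called and 1, Myb, lower over the list alone. Dendritic cell genes (6 members, median -0.21, mean -0.01, though camera's direction was higher, camera adjusted p 0.898) had 0 called and 1, Itgax, higher over the list alone. In the eosinophil list (9 members, median -0.59, camera adjusted p 0.898) Alox15 was the called member, and 3 were higher and 4 lower over the list alone. The monocyte list was called by camera under the stricter filter, without pair A and without pair B. Camera also called the eosinophil list without pair A, and the stem and progenitor and dendritic cell lists without pair B.

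The polarized library of pair C stood apart from the rest. It lay at -45.3 on the first principal component, which held 29.5% of the variance, while the other 5 lay between -8.82 and 28.1, and its TMM factor of 0.876 was the lowest. Its deviation from the mean of the 6 libraries fell with gene length (Spearman correlation across genes -0.298, against -0.05 to 0.19 in the others), and it held the highest share of mitochondrial counts (0.743%, against 0.699% in its depolarized partner). Cell cycle genes lay at a median of 1.86 above their mean over all libraries there, on the log2 scale, against -0.43 to 0.30 in the others. Of 1010 genes called without pair C that were also tested with all 3 pairs, 411 (40.7%) had the same sign in pair C, and of the 123 with an absolute log2 fold change of at least 1, 87 (70.7%) did.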

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

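The counts of called genes depended on the design, filter and tool more than on scaling. DESeq2 size factors and upper-quartile scaling left the 8 higher and 24 lower genes as they were. Counts of higher and lower genes were 50 and 96 without a filter, 3 and 5 under the stricter filter (6076 genes tested), 16 and 23 with DESeq2, 10 and 26 with limma-voom, 9 and 21 with robust estimates, 14 and 29 at a threshold of 0.10, and 5 and 24 at a log2 fold change of at least 1. The cause was not tested, except that the last setting is a subset by construction and the stricter filter tests 13 of the 32 called genes. Chosen after seeing the data, the newer edgeR method gave 14 and 38, and removing the gene length trend with the replicate block kept gave 0 and 8. There the fold changes of the 32 genes moved by at most 0.14 on the log2 scale, and the prior degrees of freedom fell from 14.7 to 8.91. As a check also added then, with 14.7 put back in that fit, 42 genes were called, 30 of the 32 among them, while standard errors of some lost genes also rose (Igha 0.61 to 0.72). With no replicate block edgeR called 0 and 0 genes, also with the newer method, and DESeq2 5 and 18. Of the 8 higher and 24 lower genes, DESeq2 called 6 and 20 with the block and 1 and 15 without it. The 32 genes kept their sign in all of these fits that tested them. This adds little, because all 32 had the same sign in each pair and the fits used the same libraries.

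Leaving out a pair gave 9 to 500 genes higher and 36 to 518 lower. Leaving out a single library with no replicate block gave 0 genes higher and 0 to 3 lower. Of the 32 genes, 30 were among the calls without pair A, 23 without pair B and 30 without pair C. Without a pair, log2 fold changes ran from -0.0256 (without pair A) to 0.347 (without C) for Cxcr2, from -0.0714 (without A) to 0.0645 (without B) for Orai1, and from -0.103 (without C) to 0.286 (without A) for Kcnj2, and the values of turned sign were not called. Of 15 called lists, 0 were called with an estimated correlation, 1 by fry and 13 with no replicate block, and 10, 10 and 8 were still called without pairs A, B and C. The macrophage list changed direction under the stricter filter (adjusted p 0.605). Depth limits genes such as Trpm4 and Kcnn4, which held fewer than 10 counts in all.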

Other observations

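Genes of other myeloid cells did not move together. Among monocyte markers, Csf1r, the receptor of macrophage colony-stimulating factor, was at 106 CPM on average in polarized and 163 CPM in depolarized cells (n = 3), and the cathepsin gene Ctss at 51.1 ± 19.7 and 80.0 ± 40.1 CPM (SD), both higher in 3 of 3 pairs. The chemokine receptor gene Ccr2 (1.38 ± 0.228 against 0.194 ± 0.294 CPM) and the transcription factor gene Irf8 (1.14 ± 0.0978 against 0.275 ± 0.173 CPM) were lower in 3 of 3. None passed the test over all genes, with edgeR adjusted p of 0.351, 0.380, 0.139 and 0.212, and all 4 passed when adjusted over the list alone. Eosinophil genes parted in the same manner: the surface genes Siglecf (log2 fold change 0.59) and Ccr3 (0.66) were fitted above 0 with Alox15, and the granule genes Epx (-2.17), Prg3 (-1.77) and Prg2 (-1.37) below 0, with edgeR adjusted p of 0.603, 0.603, 0.123, 0.202 and 0.464 for those other than Alox15. The progenitor transcription factor gene Myb was at 7.51 ± 1.39 and 3.53 ± 1.70 CPM (edgeR adjusted p 0.127), lower in 3 of 3 pairs, and the integrin gene Itgax at 10.2 ± 3.71 and 21.9 ± 5.50 CPM (edgeR adjusted p 0.133), higher in 3 of 3. All of these genes were chosen after their values were seen.

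Interferon-stimulated genes stood at different levels in the 3 pairs, a difference that was not tested. The median member lay 0.92 and 1.07 above its mean over all libraries, on the log2 scale, in the polarized and depolarized library of pair C, and between -0.77 and -0.24 in the other 4 libraries. Ifit3 was at 118 and 162 CPM in pair C, and 11.2 and 26.7 CPM in pair B (polarized and depolarized), and at 34.8 CPM in the depolarized library of pair A. Other immunoglobulin genes differed between pairs. Iglc2, which was lower with Igha over the plasma cell list alone, was at 0.459 and 1.01 CPM in pair C, 39.4 and 0.834 CPM in pair B and 10.6 and 2.36 CPM in pair A. Igkc was at 9.08 and 328 CPM in pair C, 183 and 3.86 CPM in pair B and 92.0 and 264 CPM in pair A, and Jchain at 0.561 and 28.2, 69.9 and 0.886, and 34.3 and 21.4 CPM in the same order.

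The tests of depth, other lineages, an immature share, gene length on the lists and exchanged labels were chosen only after the results were seen. Splits of the 6 libraries into 3 against 3 number 10, too few for a share under 0.05. The real split called 32 genes and 1 of the 10 gave as many, with 2 the highest of the others, and among the 3 other splits that part all 3 pairs the highest was also 2. The real split called 15 lists, 3 of the 10 gave as many, and the highest of the others was 15. The other splits that part all 3 pairs gave 6 to 13, and those with 15 part 1 pair.

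Early-stage, primary granule and cell cycle lists were lower in depolarized cells by camera with the preset correlation (adjusted p = 0.451 for each with an estimated correlation), with 16 of 28, 8 of 13 and 26 of 31 members not called. Shallower depolarized libraries are argued against, since in pairs A and B, whose depolarized library held more counts, 82.3% and 71.0% of all 62 tested members of these lists, called or not, were lower (exact binomial p 2.78e-07 and 0.00130). These p-values take the genes within a pair as independent, which members of such lists are not. They are therefore too small, and they do not measure the spread between pairs. A larger admixture of other lineages in the polarized sort is argued against for erythroid cells only. The first quartile of log2 fold changes of their 7 tested genes was -0.23, against the early-stage median of -0.95. Monocyte genes had a median of 0.14, but a mean of -0.57 and a first quartile of -1.19. Their list, not called in the main fit, was called by camera under the stricter filter, without pair A and without pair B. Plasma cell (median -1.66), macrophage (-0.87), eosinophil (-0.59), stroma (-0.58), T and NK cell (-0.44) and B cell genes (-0.41) had medians below 0. Members such as Igkc and Jchain went both ways between pairs, so a larger share of some of these cells stays open. A larger share of immature cells of the neutrophil lineage in the polarized sort stays open: that the early-stage median lay below the late-stage median in 3 of 3 pairs restates the pattern and does not support it, and bulk RNA cannot separate a share of cells from a level per cell. A difference between depolarizing and polarized neutrophils of the same stage stays open and untested.

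Of the late-stage and response lists, 6 were higher in depolarized cells by camera with the preset correlation, and 0 were called with an estimated correlation (adjusted p = 0.451 to 0.718). With 1 pair left out at a time, the interferon list was called each time, and each of the other 5 lost its call at least once. Gene length trends between libraries are argued against as the whole cause of these calls, since 6 of the 6 lists were still called with the preset correlation after the trend was removed. That test called 6 to 15 lists in the other splits of the libraries. It therefore cannot show that the lists differ between the groups for a cause other than such variation between libraries. If immature cells dilute the polarized sample, late-stage genes could rise alike by a small amount: the 35 members differed by more than their standard errors (Cochran Q against chi-square, p = 1.33e-05), but immature cells may express some of them, so dilution cannot be told apart from a change within mature cells.

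Most genes called from pairs A and B alone were not called with pair C. With the labels of 1 of those 2 pairs exchanged, 7 genes were called in place of 1018. Exchanged labels in pair C are argued against by early-stage genes only, since 100% of the 13 called lower from the other pairs were lower there too. This set was chosen after the list was seen to be lower. Of all genes called from the other pairs, 171 of 511 lower (33.5%) and 240 of 499 higher (48.1%) had the same sign in pair C. Among those with an absolute log2 fold change of at least 1, 87 of 123 (70.7%) did. Gene length trends ran in opposite directions (Spearman correlation across genes -0.170, -0.04 and 0.224 in pairs A, B and C), but with the trend removed 45.6% of 774 genes had the same sign in pair C, so length is argued against as the whole cause. A biological difference between the preparations of each pair, such as the interferon level above, was not tested and stays open.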
